A study of Mus musculus with 29 samples.

How the data were processed

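RNA was measured in stem and progenitor cells sorted from the bone marrow of C57BL/6 mice aged 8 to 12 weeks. Lineage-negative, cKit-positive, Sca1-positive cells were parted by the surface receptor CD150 into a CD150-positive and a CD150-negative population, per the labels. RNA depleted of ribosomal RNA was made into libraries with a stranded low-input kit and sequenced as paired 50-base reads, per the labels' protocols. Both sexes were used, per the labels, and the sex of single libraries was not given. The labels did not say that the libraries of a group came from separate animals, so every p-value measured only the spread between these libraries, which may be technical. In both populations A2 differed from the other A libraries in Xist and Ddx3y as animals of another sex do, so A2 and the others did not come from 1 animal. No such difference was seen within the other groups.

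The authors deposited whole-number read counts per gene symbol for 23366 genes in 29 libraries. Reads were checked with FastQC, trimmed with Trimmomatic 0.33, aligned to mouse build mm9 with TopHat2 2.0.9 and Bowtie 1.0.0, counted with featureCounts and tested with edgeR in R 3.4.2, per the submitters' processing notes. The strand setting of the counting, the annotation and the treatment of reads with several matches were not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies could therefore be assigned to the wrong gene. A deposited matrix of normalised CPM held 12578 genes with the same sum in each library. The sorted values of its libraries differed by a median of 0.00243 as a share of the value, and it served only as an alternative.

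Library totals ran from 12304713 to 54339749 counts. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 20.75 or more over genes with a summed count of at least 20. A table with all 29 libraries had 0 columns of other samples.

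Each population was fitted on its own with all 4 genotype groups, which shared 1 estimate of the spread. Genes were kept by filterByExpr with the groups, which left 21168 genes in the CD150-negative and 20944 in the CD150-positive fit, and counts were scaled by TMM. The populations of the wild-type libraries and the difference of the Mysm1 effect between populations were tested in 1 fit of all 29 libraries and 21830 genes. Genes were called with edgeR 4.0.16 by the quasi-likelihood F test at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene given here is from that test, in R 4.3.3. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic, which is an approximation. Levels are TMM-scaled CPM, except that receptor genes taken as background are in CPM of the library totals, and log2 CPM of lists used a prior count of 2.

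There were 24 gene lists of 680 gene entries, of which 12 were not matched. Each list with at least 5 tested members was compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 and, as an alternative, with a correlation estimated from the residuals. Adjusted p-values of lists were Benjamini-Hochberg values over the lists of a comparison. The rotation test fry, which asks whether the members of a list move on balance one way, was another alternative.

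The comparisons, the lists, the tests and the rule for named genes were fixed before the data were examined. Mysm1 and Bbc3 were named in every comparison. Besides them, the 8 largest rises and 8 largest falls, or 4 and 4 in comparisons other than the main ones, were named among called genes with a mean log2 CPM of at least 2. Their groups had to share no range of values, and predicted or clone names were left out. Up to 4 members with the smallest p of each described list were added. Where no gene passed, the 4 genes with the smallest p under the same level and name criteria were given as values. For differences between effects the criterion on ranges could not be applied. The choice of lists described in the text was made after their results were seen.

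Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups alone, limma voom with sample quality weights, limma-trend on log2 of the deposited CPM plus 1 for genes with a CPM of at least 1, leaving out each library in turn, a block by sample number and leaving out the libraries of a second naming series. The treatment of background reads was added after the data had been seen. Reads on olfactory, vomeronasal and trace amine receptor genes, 1471 genes in all, served as a measure of background, since these genes are not known to act in marrow cells. Libraries above 1.5 times the median of their population were left out in 1 alternative, and log2 of this level was a covariate in the other.

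The tests were run on simulated counts with 200 genes changed by known folds. For Mysm1 loss in CD150-negative cells 28.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 12 false calls among 141 and 20499 genes tested. For Mysm1 loss in CD150-positive cells the shares were 5.97%, 47.8% and 93.9%, with 3 false calls among 101 and 20225 genes. For Puma loss on Mysm1 loss they were 19.4%, 58.2% and 98.5% in CD150-negative cells and 14.9%, 68.7% and 98.5% in CD150-positive cells. A simulated rise of a list of 35 genes was called with either correlation, and none of the other lists was. The simulated genes were drawn independently of each other, so this did not test list calls among correlated genes. Coordinates are those of NCBIM37, the assembly also called mm9, with the GENCODE M1 annotation.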

Results

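Gene expression was measured by RNA sequencing in blood stem and progenitor cells of mice lacking Mysm1, which encodes a deubiquitinase of histone H2A, or Bbc3, which encodes the cell death protein Puma, a target of p53. The series title names Bbc3 as a p53 target held in check by MYSM1 and links it to the survival of multipotent progenitors and the upkeep of stem cells. In CD150-negative cells, the fraction that holds multipotent progenitors, 3 libraries each were labelled wild type, Puma-/-, Mysm1-/-Puma-/- and Mysm1-/-Puma+/-. In CD150-positive cells, the fraction that holds stem cells, 4 libraries were labelled Mysm1-/-Puma+/-, 7 Mysm1-/-Puma-/-, 2 Puma-/- and 4 wild type. The submitters used Mysm1-/-Puma+/- mice in place of Mysm1-/- mice. Libraries carry the submitters' names, with A for Mysm1-/-Puma+/-, B or P for Mysm1-/-Puma-/-, C for Puma-/- and D or W for wild type. Library totals ran from 28066870 to 54339749 counts in CD150-negative cells and from 12304713 to 35034318 in CD150-positive cells.

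Mysm1, on chromosome 4 from 94608731 to 94645791 on the minus strand of NCBIM37, was detected in every library. In CD150-negative cells its CPM was 125, 102 and 78.7 in A1, A2 and A3, 74.1, 67.4 and 69.6 in B1, B3 and B5, 96.2, 93.3 and 85.1 in C2, C3 and C5, and 110, 103 and 100 in D2, D3 and D4. In CD150-positive cells it was 118, 101.05, 103 and 96.3 in A1 to A4, and 84.3, 86.3, 72.3, 87.4, 76.6, 67.7 and 87.7 in B1, B3, B5, B6, P1, P2 and P3. It was 132 and 120 in C1-4 and C2-5, and 111, 118, 125 and 123 in D1, D2, D3-4 and W1. Bbc3, on chromosome 7 from 16894965 to 16903554 on the plus strand, was higher in every library labelled Mysm1-/- than in any library with wild-type Mysm1 of the same population. Its CPM in CD150-negative cells was 21.3, 27.8 and 46.5 in A1 to A3, 20.2, 26.0 and 29.7 in B1, B3 and B5, 6.14, 5.21 and 5.34 in C2, C3 and C5, and 4.29, 8.10 and 7.14 in D2 to D4. In CD150-positive cells it was 18.5, 19.2, 24.9 and 18.6 in A1 to A4, and 16.3, 19.9, 18.6, 15.5, 25.2, 18.0 and 22.0 in B1, B3, B5, B6, P1, P2 and P3. It was 2.68 and 2.10 in C1-4 and C2-5, and 4.16, 3.36, 2.86 and 4.63 in D1, D2, D3-4 and W1. The labels did not say which exons the mutant alleles lack, so counts over whole genes checked neither genotype. Neither gene overlapped another annotated gene.

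**Figure D1:**
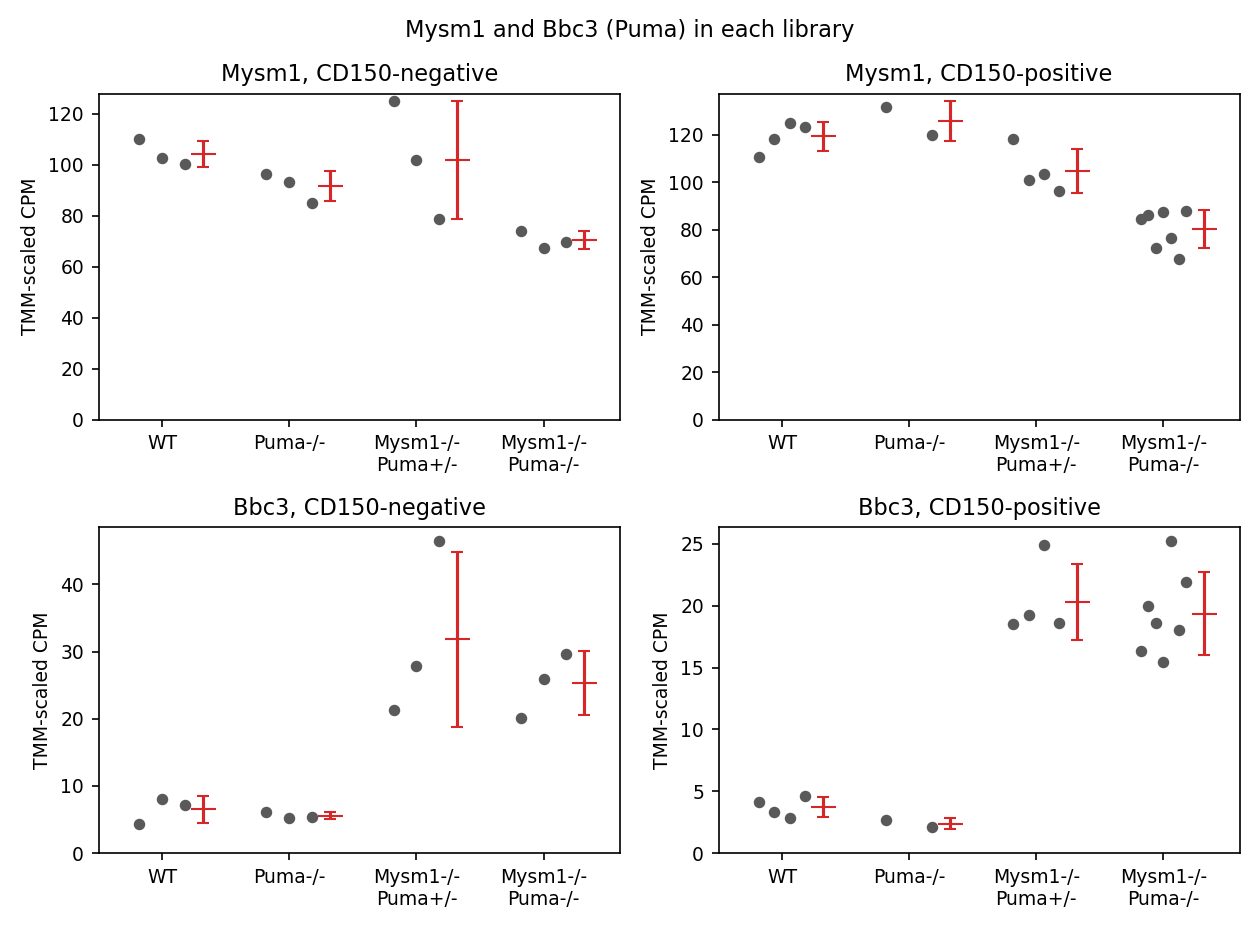
TMM-scaled CPM of Mysm1 and Bbc3 in each library, by labelled genotype and population; each point is a library, and the red marks are the group mean ± SD. Bbc3 lay between 15.5 and 46.5 in libraries labelled Mysm1-/- and between 2.10 and 8.10 in the others.

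Several libraries stood apart from others of their group. Xist, the RNA of the inactive X chromosome, was at 446 CPM in the CD150-negative and 348 CPM in the CD150-positive library A2 and at 13.1 or less in all others. Ddx3y, a Y-linked gene, was at 0.0823 and 0.589 in both A2 libraries and at 61.7 or more elsewhere. Transcripts of olfactory, vomeronasal and trace amine receptors, taken as background, ranged from 622 to 9003 CPM of the library totals, without TMM scaling. In CD150-negative cells they spanned 1042 to 3078 CPM in A, 2923 to 5810 in B, 2125 to 4148 in C and 1993 to 4296 in D. In CD150-positive cells they spanned 1420 to 3449 in A, 622 to 7491 in B and P, 4192 to 9003 in C and 2564 to 8186 in D and W. B1 of CD150-negative cells (5810) and B5 (7491), C2-5 (9003) and D2 (8186) of CD150-positive cells exceeded 1.5 times the median of their population. Fos, an immediate early gene, was at 11.5, 62.3, 120 and 218 CPM in P1, P2, P3 and W1 and at 4.56 or less in the other CD150-positive libraries. P and W formed a second naming series, which held 3 Mysm1-/-Puma-/- libraries and 1 wild-type library, too few for values of its own. Counts and list medians of CD150-positive cells without it are therefore given beside the pooled ones, with single genes where it ended a call.

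The wild-type libraries showed how the sorted populations differ. Slamf1, which encodes CD150, had 19.3 ± 2.54 CPM (SD, n = 4) in CD150-positive and 0.671 ± 0.316 (n = 3) in CD150-negative cells, a log2 fold change of 4.83 ± 0.42 (SE) at an adjusted p of 5.3e-09. The largest rises were in Nol3, an apoptosis repressor (9.40), Phkg1, a phosphorylase kinase subunit (6.89), Tmod1, which caps actin filaments (6.74), Sdpr (6.42), Pf4, platelet factor 4 (5.79), Ccdc144b (4.97), Slamf1 and Vwf, which encodes von Willebrand factor (4.29). The largest falls were in Psg28 (-6.14), a member of a family of near-identical genes and so uncertain, Ptger1, a prostaglandin E receptor (-5.23), Dntt, the terminal transferase of lymphoid cells (-4.76), Gas7 (-4.67), Myoz3 (-4.57), Mcc (-4.25), and, next in size, Ednrb, an endothelin receptor, and Mylk2. Of 30 stem cell genes 21 rose and 2 fell (23 and 2 adjusted over the list alone; median 1.41, and 1.10 without the P and W libraries; adjusted p = 4.95e-22, and 0.0163 with an estimated correlation), among them Gata2 (2.04 ± 0.17) and Tek (2.73 ± 0.23). Of 21 megakaryocyte genes 12 rose (15 up and 1 down adjusted over the list alone; median 1.92, and 2.00 without those libraries; adjusted p = 3.5e-17, and 0.0272 with an estimated correlation), among them Itga2b, an integrin subunit (2.99 ± 0.25), and Trpc6 (3.10 ± 0.28). Of 19 multipotent progenitor and lymphoid priming genes 13 fell (16 adjusted over the list alone; median -1.34, and -1.43 without those libraries; adjusted p = 3.5e-17, and 0.00684 with an estimated correlation). Among them were Notch1 (-2.73 ± 0.30), Satb1 (-3.59 ± 0.41) and Flt3, the receptor of a progenitor growth factor (-3.62 ± 0.43). Of 19 erythroid genes 4 rose (8 adjusted over the list alone), among them Hemgn (1.24 ± 0.18) and Gata1 (2.68 ± 0.54), and the list lay higher (median 1.24, and 1.17 without those libraries; adjusted p = 2e-05, but adjusted p = 0.707 with an estimated correlation). Over all genes 675 rose and 885 fell, and without the P and W libraries 626 rose and 998 fell. The total of 1560 became 984 without the CD150-negative library D2 and 1035 without D4. Bbc3 was at -0.76 ± 0.24 with an adjusted p of 0.0522, which became 0.039 without W1, 0.029 without the P and W libraries and 0.016 without the CD150-negative library D2. Mysm1 was at 0.23 ± 0.13 (adjusted p = 0.372).

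Loss of Mysm1 was examined by comparing libraries labelled Mysm1-/-Puma+/- with wild type, which addresses what MYSM1 holds in check. These groups also differ in Puma, so an effect of Puma heterozygosity cannot be parted from that of Mysm1 loss here. In CD150-negative cells (3 against 3 libraries) 21 of 41 targets of p53 rose (29 adjusted over the list alone), with a median log2 fold change of 0.82 over the list (adjusted p = 6.9e-41, and 0.000377 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 2.37 ± 0.0632 to 33.2 ± 4.16 CPM (SD, n = 3 each; log2 fold change 3.80 ± 0.24 SE, adjusted p = 4.1e-08). Bbc3 rose from 6.51 ± 1.98 to 31.9 ± 13.1 CPM (2.28 ± 0.28, adjusted p = 0.00018), while Mysm1 was at 104 ± 5.07 and 102 ± 23.1 CPM (-0.03 ± 0.15, adjusted p = 0.972). The other large rises were in Eda2r, a receptor of the tumour necrosis factor family (5.22 ± 0.38), Tnfsf4, the ligand OX40L (4.47 ± 0.58), Ak1, adenylate kinase 1 (3.82 ± 0.17), and Epha2, an ephrin receptor (3.81 ± 0.25). Next came Serpine2, a protease inhibitor (3.66 ± 0.21), Pvt1, a noncoding RNA (3.57 ± 0.37), and Phlda3, a repressor of Akt (3.52 ± 0.23). The adjusted p-values of these genes lay between 7.5e-10 and 0.00035. Psrc1, another p53 target, rose by 2.27 ± 0.13. The largest falls were in Hnf4a, a nuclear receptor (-2.65 ± 0.17), Rftn2 (-2.29 ± 0.38), Obsl1 (-2.16 ± 0.33), Plag1, a transcription factor (-2.13 ± 0.35), Slc27a2, a fatty acid transporter (-1.99 ± 0.41), Plxdc2 (-1.79 ± 0.31), Ccr9, a chemokine receptor (-1.77 ± 0.37), and Pdzd4 (-1.63 ± 0.29).

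Of 26 genes of the Bcl2 and caspase list, which shares 4 members with the p53 targets, 3 rose in CD150-negative cells (6 adjusted over the list alone), and all 3 are also on the p53 list. They were Bbc3, Bax (1.87 ± 0.16) and Pmaip1, which encodes Noxa (3.11 ± 0.35), and the list lay higher (adjusted p = 4.3e-05, but adjusted p = 0.237 with an estimated correlation). Of 21 megakaryocyte genes 1 rose, Selp, which encodes P-selectin (2.33 ± 0.30), with 7 adjusted over the list alone, and the list lay higher (adjusted p = 2e-06, but adjusted p = 0.237 with an estimated correlation). Of 30 stem cell genes 2 rose and 2 fell (5 and 5 adjusted over the list alone). Of 78 cytosolic ribosomal protein genes 3 fell (7 adjusted over the list alone), and the list test had an adjusted p of 0.323. No erythroid or mitosis gene was called by edgeR, with 1 of 19 and 2 of 37 lower at an unadjusted p under 0.05, and both lists lay lower (medians -0.46 and -0.17, adjusted p = 0.00522 and 0.00274, but adjusted p = 0.784 and 0.837 with an estimated correlation). The erythroid list was not called without A1 or A2 (0.198 and 0.290), nor the mitosis list without A3 or D2 (0.357 and 0.0761). Its mean log2 CPM, for the erythroid list, ran from 1.74 to 4.16 in A and from 3.48 to 3.78 in wild type. The A libraries thus lay on both sides of the wild-type range. Igj, an immunoglobulin joining chain gene of the B lineage named after its values were seen, rose from 105 ± 40.1 to 939 ± 513 CPM (3.16 ± 0.59, adjusted p = 0.0119). That call ended without D2 or D4 (0.0848 and 0.0686), and the B cell list had a median of -0.00801 (adjusted p = 0.983). In CD150-positive cells Igj varied widely within groups, in CPM of the library totals. It ran from 35.4 to 623 in A, from 12.9 to 2494 in B and P and from 43.3 to 183 in D and W. It was at 702 and 362 in C1-4 and C2-5, so libraries with and without Mysm1 overlapped there. In total 135 genes rose and 49 fell, 184 together, against 427 by DESeq2, 858 by voom, 297 by limma-trend and 394 with background as a covariate. Leaving out A3 gave 328, D4 98, D2 109 and A1 118. The calls of Slc27a2, Ccr9 and Pdzd4 ended without A1 (adjusted p of 0.14, 0.11 and 0.052), A2 (0.14, 0.13 and 0.053) or D4 (0.10, 0.17 and 0.052). That of Slc27a2 also ended without D2 (0.054) or D3 (0.10), and that of Ccr9 without D3 (0.077).

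In CD150-positive cells the same comparison (4 against 4 libraries) gave 16 rises and 1 fall among 41 p53 targets (28 and 1 adjusted over the list alone), with a list median of 0.70 (adjusted p = 1.5e-32, and 4.17e-05 with an estimated correlation; without the P and W libraries 0.78). The target that fell was Ptpn14, a phosphatase (-1.22 ± 0.267, adjusted p = 0.0406), a call that ended without A1, A2, A3, D1, D3-4 or W1 (0.131, 0.104, 0.0524, 0.0672, 0.158 and 0.0941) and without the P and W libraries (0.0529). Cdkn1a rose from 1.36 ± 0.801 to 19.2 ± 5.33 CPM (SD, n = 4 each; 3.81 ± 0.37 SE, adjusted p = 5.3e-06, and 4.24 without the P and W libraries). Bbc3 rose from 3.75 ± 0.79 to 20.3 ± 3.06 CPM (2.43 ± 0.23, adjusted p = 4.6e-06, and 2.54 without those libraries). Mysm1 was at 119 ± 6.26 and 105 ± 9.44 CPM (-0.19 ± 0.13, adjusted p = 0.668). Large rises were also seen in Sulf2, a sulfatase of heparan sulfate (4.35 ± 0.48), Eda2r (3.61 ± 0.54), Phlda3 (3.09 ± 0.39), Gem, a small GTPase (2.88 ± 0.49), Epha2 (2.56 ± 0.52) and Mmp2, a gelatinase (2.38 ± 0.26). The p53 targets Psrc1 (2.27 ± 0.21) and Ccng1, cyclin G1 (1.62 ± 0.16), rose as well. The largest falls were in Trib2, a pseudokinase (-2.46 ± 0.46), Ephb4, an ephrin receptor (-2.21 ± 0.39), Tenc1 (-1.92 ± 0.42), Zfp651 (-1.88 ± 0.38), Hnf4a (-1.87 ± 0.31), Plxdc2 (-1.80 ± 0.27), Socs2, a suppressor of cytokine signalling (-1.68 ± 0.37), and Jam3, a junction protein (-1.56 ± 0.33). Of 26 genes of the Bcl2 and caspase list 3 rose, Bbc3, Bax (1.33 ± 0.18) and Apaf1 (0.77 ± 0.14), with 4 adjusted over the list alone (list adjusted p = 6.5e-05, but adjusted p = 0.199 with an estimated correlation; median 0.22 without the P and W libraries). Of 21 megakaryocyte genes 2 rose, Selp (2.15 ± 0.26) and Clec1b (2.01 ± 0.45), with 10 adjusted over the list alone (list adjusted p = 1.5e-10, but adjusted p = 0.259 with an estimated correlation; median 0.56 without the P and W libraries). Of 78 ribosomal protein genes 1 fell, Rpl36a (-0.77 ± 0.17), also 1 adjusted over the list alone (median -0.0740, adjusted p = 0.0302, but adjusted p = 0.787 with an estimated correlation; -0.15 without the P and W libraries). Of 35 interferon response genes 1 rose, Igtp (0.93 ± 0.18), with 9 adjusted over the list alone (median 0.39, adjusted p = 0.000231, but adjusted p = 0.787 with an estimated correlation; 0.51 without the P and W libraries). The ribosomal protein list was no longer called without A2, A4, D1 or D3-4 (adjusted p 0.0545, 0.825, 0.110 and 0.688), nor the interferon list without A4 (0.614). Mitosis genes lay higher and erythroid genes lower as lists (medians 0.24 and -0.38, adjusted p = 0.0110 and 0.00645, but adjusted p = 0.787 for both with an estimated correlation). No member was called by edgeR, with 2 of 37 mitosis genes higher and 1 of 19 erythroid genes lower at an unadjusted p under 0.05. These medians without the P and W libraries were 0.18 (adjusted p = 0.176) and -0.49. The mitosis list was not called without A1, A2 or W1 (0.967, 0.206 and 0.182), nor the erythroid list without A1 or A2 (0.413 and 0.149). The mean log2 CPM of the erythroid list ran from 2.36 to 5.34 in A, on both sides of the wild-type range of 4.54 to 4.95. In total 78 genes rose and 17 fell, against 57 and 15 without the P and W libraries and 155 and 89 by DESeq2, and leaving out A1 gave 60 calls in place of 95. The call of Epha2 ended without A1, A2, D1, D2 or D3-4 (adjusted p 0.083, 0.054, 0.081, 0.090 and 0.088). Zfp651 ended without A1, A2, A3 or D2 (0.082, 0.068, 0.085 and 0.074), and Tenc1 without A1, A2, A3, D3-4 or W1 (0.17, 0.11, 0.15, 0.088 and 0.19). Socs2 ended without A1, A3, A4, D2, D3-4 or W1 (0.11, 0.16, 0.12, 0.051, 0.14 and 0.14). Jam3 ended without A1, A2, A3, D1, D3-4 or W1 (0.069, 0.090, 0.12, 0.077, 0.071 and 0.069), and Clec1b without A3, A4, D1, D2, D3-4 or W1 (0.17, 0.15, 0.14, 0.079, 0.14 and 0.14). Rpl36a ended without A1, A2, A3, A4, D1, D2 or D3-4 (0.0545, 0.132, 0.132, 0.123, 0.0950, 0.0889 and 0.214), and Igtp without A3, A4, D1, D2 or D3-4 (0.102, 0.0554, 0.0667, 0.0778 and 0.0578). Without the P and W libraries the calls of Tenc1, Socs2, Clec1b and Igtp ended (0.147, 0.120, 0.114 and 0.0645).

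**Figure D2:**
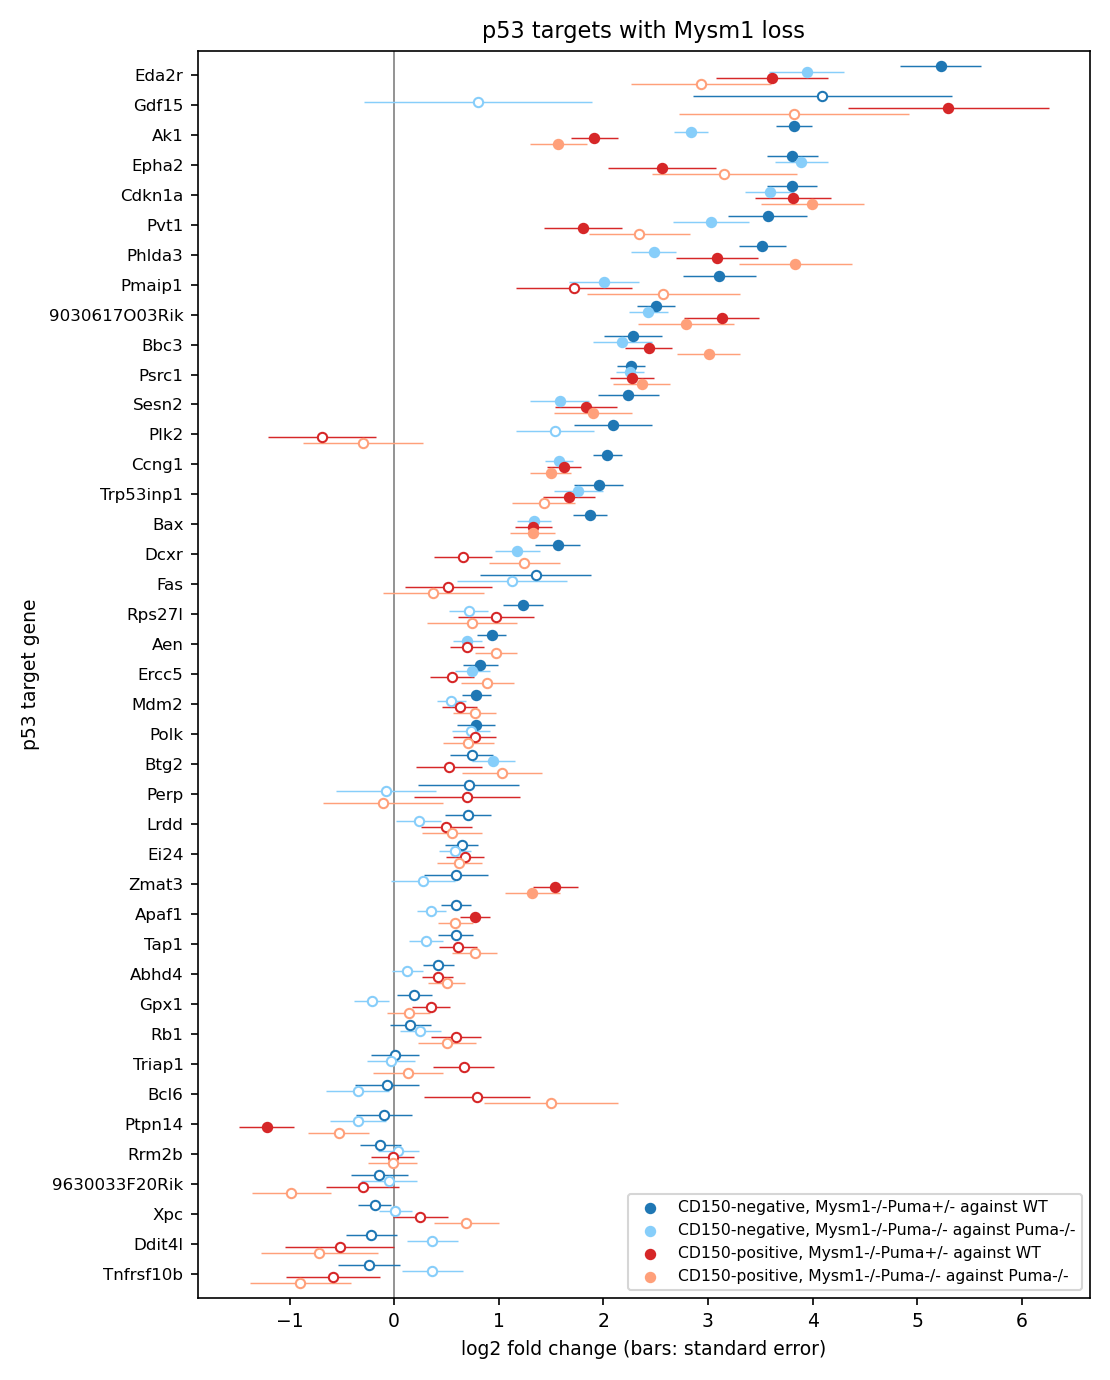
Log2 fold change ± SE of 41 p53 targets with Mysm1 loss, as Mysm1-/-Puma+/- minus wild type and as Mysm1-/-Puma-/- minus Puma-/-, in CD150-negative and CD150-positive cells; filled points have an adjusted p under 0.05 and open points do not. Against wild type 21 targets rose in CD150-negative cells, and 16 rose and 1 fell in CD150-positive cells.

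Loss of Puma in cells without Mysm1 was examined by comparing libraries labelled Mysm1-/-Puma-/- with those labelled Mysm1-/-Puma+/-. In CD150-negative cells (3 against 3) transcripts of dividing cells were lower. Of 37 mitosis genes 24 fell (35 adjusted over the list alone), with a list median of -0.79 (adjusted p = 2.2e-28, but adjusted p = 0.256 with an estimated correlation). Among them were Ccna2, cyclin A2 (-1.04 ± 0.17), Kif20a (-0.81 ± 0.16) and, between these in size, Kif2c and the checkpoint kinase Bub1. The mean log2 CPM of this list was 6.40 ± 0.23 (SD, n = 3) in A, 5.65 ± 0.26 in B, 6.41 ± 0.11 in C and 6.59 ± 0.11 in D. Of 37 DNA replication genes 3 fell (34 down and 1 up adjusted over the list alone; median -0.61, adjusted p = 1.6e-18), Rrm2 (-1.12 ± 0.18), Prim1 (-0.77 ± 0.16) and Rrm1 (-0.83 ± 0.19). Of 78 cytosolic ribosomal protein genes 5 fell (69 adjusted over the list alone; median -0.50, adjusted p = 2.8e-34), among them Rpl37a (-0.60 ± 0.14) and Rpl8 (-0.70 ± 0.17), which like others of this list have near-identical pseudogenes and are uncertain. Of 47 oxidative phosphorylation genes 9 fell (47 adjusted over the list alone; median -0.62, adjusted p = 9.1e-30), among them Atp5o (-0.79 ± 0.15), Cox7b (-0.84 ± 0.17), Ndufb5 (-0.76 ± 0.16) and Ndufb2 (-0.98 ± 0.21). Each of these last 3 lists had an adjusted p = 0.256 with an estimated correlation. Receptor transcripts taken as background were at 2993, 3078 and 1042 CPM in A1, A2 and A3 and at 5810, 2923 and 3192 in B1, B3 and B5. Their higher mean in B thus rested mainly on A3 and B1. Of 41 p53 targets 2 fell, Rps27l (-0.84 ± 0.19) and Bax (-0.66 ± 0.16), with 4 adjusted over the list alone (median -0.24, adjusted p = 0.00025, but adjusted p = 0.256 with an estimated correlation). The Bcl2 and caspase list had Bax as its only fall, with 4 adjusted over the list alone (median -0.26, adjusted p = 0.00102, but adjusted p = 0.284 with an estimated correlation).

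Single genes with the largest falls in this comparison were Gem (-1.57 ± 0.19, adjusted p = 0.0041), Emilin2, a matrix protein (-1.48 ± 0.23), Clec10a, a lectin (-1.40 ± 0.31), and Ptgr1, a prostaglandin reductase (-1.38 ± 0.25). These were followed by Ppic, a cyclophilin (-1.33 ± 0.26), Mnd1, which acts in meiotic recombination (-1.31 ± 0.23), Hist2h2bb, a histone gene with near-identical copies and so uncertain (-1.26 ± 0.17), and Pbk, a mitotic kinase (-1.22 ± 0.22). The largest rises were in Slc35d3 (2.07 ± 0.35), Sema3d, a semaphorin (2.01 ± 0.42), Sox11, a transcription factor (1.90 ± 0.34), and Plag1 (1.60 ± 0.34). Next were Obsl1 (1.52 ± 0.32), Vmn2r35, a vomeronasal receptor of the genes used to measure background and so uncertain (1.52 ± 0.36), Scube3 (1.49 ± 0.34) and Auts2 (1.37 ± 0.20). Mysm1 was at 102 ± 23.1 in A and 70.4 ± 3.39 CPM in B (-0.53 ± 0.15, adjusted p = 0.0748, and 0.0082 without A3), and Bbc3 at 31.9 ± 13.1 and 25.3 ± 4.77 (-0.33 ± 0.26, adjusted p = 0.573). In total 41 genes rose and 222 fell, 263 together, against 1404 by DESeq2, 1724 by voom, 363 by limma-trend and 316 with background as a covariate. The total of 263 became 1 without A2, 47 without A1, 64 without B1, 89 without B3, 1086 without A3, 942 without B5 and 2 when the compared groups were fitted alone. With A2 left out only Gem, of all genes named above with a fall or rise, was still called, while the others had adjusted p-values from 0.057 for Auts2 to 0.23 for Bax. Leaving out A1 or B1 ended the same calls except those of Auts2, Emilin2, Hist2h2bb, Ccna2, Kif2c and Rrm2 (adjusted p from 0.053 to 0.17 and from 0.054 to 0.23). Leaving out B3 ended those of 8 of the largest changes (0.063 to 0.14) and of Kif20a, Prim1, Rrm1, Rpl37a, Rpl8, Rps27l, Bax and the 4 oxidative phosphorylation genes (0.061 to 0.14). The call of Vmn2r35 also ended without A3 (0.0501). The median of all genes in this comparison was 0.09 with TMM and -0.02 in the deposited CPM, a shift smaller than the changes of these lists.

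**Figure D3:**
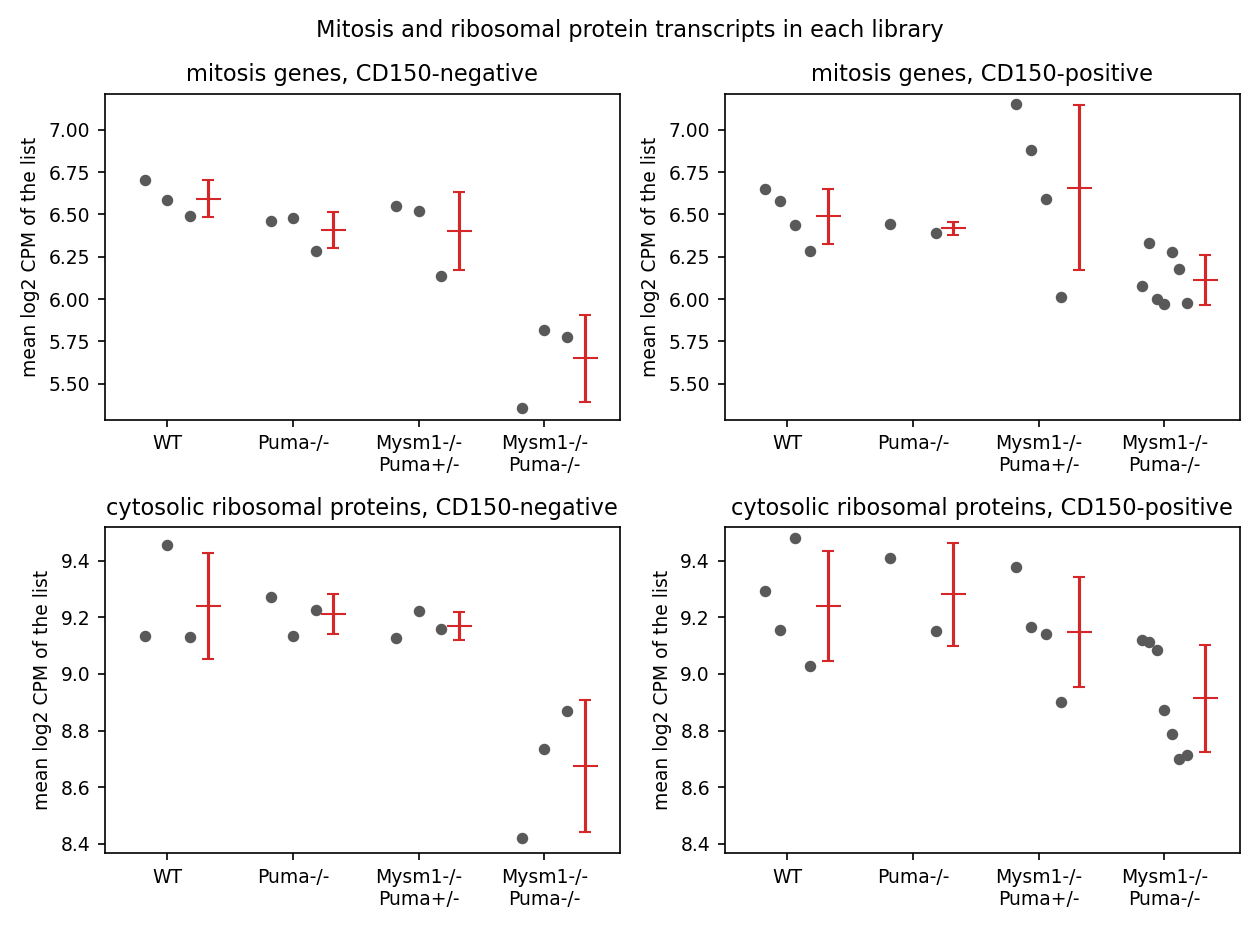
Mean log2 CPM of the mitosis genes and of the cytosolic ribosomal protein genes in each library, by labelled genotype and population; each point is a library, and the marks are the group mean ± SD. In CD150-negative cells the mitosis list lay at 5.65 ± 0.26 in Mysm1-/-Puma-/- libraries and at 6.40 ± 0.23 in Mysm1-/-Puma+/- libraries.

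In CD150-positive cells (7 against 4) the mitosis list also lay lower in libraries labelled Mysm1-/-Puma-/-, with a median of -0.59 (-0.61 without the P and W libraries) and 34 of 37 members called when adjusted over the list alone (adjusted p = 2.4e-34, but adjusted p = 0.213 with an estimated correlation). The mean log2 CPM of this list was 6.66 ± 0.49 (SD, n = 4) in A, 6.11 ± 0.15 (n = 7) in B and P, 6.42 ± 0.0386 (n = 2) in C and 6.49 ± 0.16 (n = 4) in D and W. The ranges of A (6.01 to 7.15) and of B and P (5.97 to 6.33) overlapped. The oxidative phosphorylation list had a median of -0.30 (adjusted p = 6e-17), the ribosomal protein list -0.22 (adjusted p = 1.7e-16) and the DNA replication list -0.32 (adjusted p = 9.5e-08, and 0.12 without A1). With an estimated correlation these had adjusted p = 0.467, adjusted p = 0.467 and adjusted p = 0.53, and without the P and W libraries their medians were -0.25, -0.11 and -0.42. Immediate early genes lay higher, with a median of 0.70 (adjusted p = 3.8e-09, but adjusted p = 0.467 with an estimated correlation), which was 0.14 without the P and W libraries. No single gene was called by edgeR over all genes, with 797 at an unadjusted p under 0.05, and DESeq2 called 3, voom 0 and limma-trend 0. By edgeR 0 were also called without the P and W libraries, with 960 at an unadjusted p under 0.05. The smallest p-values belonged to Plxdc2 (1.304 ± 0.25), Selp (-1.07 ± 0.22) and Skint3 (1.81 ± 0.37), each at an adjusted p of 0.482, and Gem (-1.86 ± 0.39, adjusted p = 0.501). Without A4, Gem reached -2.15 at an adjusted p of 0.036, and 9 genes were called. Mysm1 was at -0.38 ± 0.11 and Bbc3 at -0.07 ± 0.19 (adjusted p = 1.00 for both), with 20.3 ± 3.06 CPM of Bbc3 in A and 19.4 ± 3.36 in B and P.

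Loss of both genes was examined by comparing libraries labelled Mysm1-/-Puma-/- with wild type. In CD150-negative cells (3 against 3) p53 targets were higher and transcripts of division and of the ribosome lower. Of 41 p53 targets 20 rose (25 adjusted over the list alone; median 0.81, adjusted p = 1.1e-28, and 0.00148 with an estimated correlation). Among them were Ak1 (3.24 ± 0.17), Psrc1 (2.15 ± 0.13), Cdkn1a (3.57 ± 0.23), Epha2 (3.57 ± 0.24) and Bbc3 (1.95 ± 0.28, adjusted p = 0.00075). Of 37 mitosis genes 34 fell (36 adjusted over the list alone; median -0.98, adjusted p = 5.7e-41, but adjusted p = 0.0924 with an estimated correlation). Among them were Ccna2 (-1.19 ± 0.17), Mki67, the marker Ki-67 (-1.06 ± 0.16), Nusap1 (-1.05 ± 0.16) and Cdca8 (-1.24 ± 0.19). Of 78 ribosomal protein genes 38 fell (51 adjusted over the list alone; median -0.60, adjusted p = 1.5e-38, but adjusted p = 0.236 with an estimated correlation). Among them were Rpl37a (-1.29 ± 0.14), Rpl36a (-1.36 ± 0.16), Rpl31 (-0.91 ± 0.12) and Rps15 (-1.07 ± 0.14), each with possible pseudogene copies. Of 37 DNA replication genes 15 fell (35 adjusted over the list alone; median -0.67, adjusted p = 1.4e-24, but adjusted p = 0.219 with an estimated correlation). Of 35 interferon response genes 1 rose (4 adjusted over the list alone; median 0.44, adjusted p = 7.8e-07, but adjusted p = 0.422 with an estimated correlation). The erythroid list lay lower (median -0.96, adjusted p = 0.000915, but adjusted p = 0.485 with an estimated correlation). The interferon gene was Zbp1 (1.16 ± 0.29), a call that ended without B1, B3, B5, D2, D3 or D4 (adjusted p 0.15, 0.20, 0.055, 0.18, 0.11 and 0.15). Besides Epha2 and Cdkn1a the largest rises were in Eda2r (4.72 ± 0.38) and Tnfsf4 (3.76 ± 0.56). The largest falls were in Rftn2 (-1.72 ± 0.37), Hnf4a (-1.59 ± 0.16), Hist1h1b, a histone gene with near-identical copies (-1.48 ± 0.16), and Rpl22l1, which encodes a paralogue of a ribosomal protein (-1.48 ± 0.19). Mysm1 was at -0.57 ± 0.15 (adjusted p = 0.0557). Igj rose by 2.72 ± 0.58 (adjusted p = 0.0166), a call that ended without B3, D2 or D4 (0.134, 0.105 and 0.0550). It was at 569, 1365 and 138 CPM in B1, B3 and B5, and B5 was level with D3 (135). In total 149 genes rose and 341 fell, 490 together, against 1029 by DESeq2, 1105 by voom, 906 by limma-trend and 837 with background as a covariate. Leaving out D2 gave 250, B1 258, D3 261 and B3 292. The call of Rftn2 ended without B1 (adjusted p = 0.12), B5 (0.059), D3 (0.081) or D4 (0.064).

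In CD150-positive cells (7 against 4) 15 of 41 p53 targets rose (28 up and 1 down adjusted over the list alone; median 0.66, adjusted p = 2.2e-41, and 1.07e-05 with an estimated correlation; 0.64 without the P and W libraries). Cdkn1a rose by 4.08 ± 0.36, Bbc3 by 2.36 ± 0.21 and Psrc1 by 2.24 ± 0.20 (adjusted p = 1.4e-06 for each), and Ccng1 by 1.51 ± 0.15. Sulf2 (4.15 ± 0.46), Eda2r (3.57 ± 0.51) and Phlda3 (3.30 ± 0.38) were the other largest rises. Of 78 ribosomal protein genes 2 fell, Rpl36a (-1.08 ± 0.15) and Rpl29 (-0.70 ± 0.13), with 28 adjusted over the list alone (median -0.34, adjusted p = 3.9e-16, but adjusted p = 0.444 with an estimated correlation; -0.29 without the P and W libraries). Rpl22l1 (-1.08 ± 0.19) and the elongation factor gene Eef1g (-1.01 ± 0.16) also fell, and these 4 genes have near-identical copies. The mitosis list had a median of -0.35 (adjusted p = 2.3e-10, but adjusted p = 0.444 with an estimated correlation; -0.45 without the P and W libraries). The interferon response list had a median of 0.42 with 1 rise, Igtp (0.90 ± 0.17), and 8 adjusted over the list alone (adjusted p = 1.7e-11, but adjusted p = 0.404 with an estimated correlation; 0.52 without the P and W libraries). Mysm1 fell from 119 ± 6.26 to 80.3 ± 8.08 CPM (-0.57 ± 0.11, adjusted p = 0.0198), a call that ended without P1 (0.059), P2 (0.055), D2 (0.062), D3-4 (0.092) or W1 (0.053), and without all P and W libraries (-0.53, adjusted p = 0.374). In total 52 genes rose and 9 fell, against 35 and 3 without the P and W libraries, 60 and 21 with RLE factors and 144 and 63 by DESeq2. The calls of Rpl22l1 and Rpl29 ended without D3-4 (0.056 and 0.071) and without the P and W libraries (0.15 and 0.28). That of Igtp ended without D1, D2 or D3-4 (0.059, 0.066 and 0.051) and without the P and W libraries (0.16).

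Loss of Puma alone was examined by comparing libraries labelled Puma-/- with wild type, and no gene was called in either population. In CD150-negative cells (3 against 3) 324 genes had an unadjusted p under 0.05, with 2 called by DESeq2, 0 by voom and 0 by limma-trend. The smallest p-values were those of Entpd4 (0.93 ± 0.19), Fgfbp3 (1.23 ± 0.28), Ide, the insulin-degrading enzyme (0.67 ± 0.17) and Sox11 (-1.31 ± 0.34), and Bbc3 was at -0.23 ± 0.27 and Mysm1 at -0.19 ± 0.15. Mitosis genes lay lower as a list (median -0.19, adjusted p = 1.7e-05, but adjusted p = 0.976 with an estimated correlation; adjusted p = 0.10 without C5). Macrophage and dendritic cell genes lay higher (median 0.46, adjusted p = 8.7e-06, but adjusted p = 0.288 with an estimated correlation). In CD150-positive cells (2 against 4) 255 genes had an unadjusted p under 0.05 and DESeq2, voom and limma-trend called 0. The smallest p-values were those of Apob, apolipoprotein B (2.64 ± 0.70), Fgfbp3 (1.48 ± 0.45), Mmp8 (2.39 ± 0.77) and Smurf1, a ubiquitin ligase (0.59 ± 0.19), and Bbc3 was at -0.64 ± 0.29 and Mysm1 at 0.08 ± 0.16. Apob was at 6.83 CPM in C1-4 and 49.5 in C2-5. Every gene named here had an adjusted p of 1.00, and without the P and W libraries 227 genes had an unadjusted p under 0.05 and 0 were called.

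Loss of Mysm1 in cells without Puma was examined by comparing libraries labelled Mysm1-/-Puma-/- with those labelled Puma-/-. In CD150-negative cells (3 against 3) 18 of 41 p53 targets rose (24 adjusted over the list alone; median 0.73, adjusted p = 1.4e-26, and 0.00195 with an estimated correlation). Tnfsf4 (4.61 ± 0.60), Eda2r (3.94 ± 0.36), Epha2 (3.89 ± 0.25) and Cdkn1a (3.59 ± 0.23) had the largest rises, and Bbc3 rose by 2.18 ± 0.28 (adjusted p = 0.00046). Of 37 mitosis genes 23 fell (35 adjusted over the list alone; median -0.80, adjusted p = 1.8e-34, but adjusted p = 0.134 with an estimated correlation), among them Mki67 (-0.95 ± 0.16) and Cdca3 (-1.04 ± 0.19). Of 78 ribosomal protein genes 34 fell (47 adjusted over the list alone; median -0.59, adjusted p = 4.7e-39, but adjusted p = 0.227 with an estimated correlation). Of 37 DNA replication genes 4 fell (30 adjusted over the list alone; median -0.61, adjusted p = 1.6e-21, but adjusted p = 0.227 with an estimated correlation). Of 35 interferon response genes 2 rose (12 adjusted over the list alone; median 0.56, adjusted p = 7.2e-09, but adjusted p = 0.355 with an estimated correlation). The erythroid list lay lower, at a mean log2 CPM of 2.76 ± 0.47 in B and 3.91 ± 0.39 in C (SD, n = 3 each). No member was called by edgeR over all genes, with 9 of 19 lower at an unadjusted p under 0.05 and 4 lower when adjusted over the list alone. The median was -1.18 (adjusted p = 1.8e-06, but adjusted p = 0.355 with an estimated correlation). Igj was at 2.16 ± 0.57 (adjusted p = 0.0814). The largest falls were in Sapcd2 (-1.50 ± 0.32), Hnf4a (-1.46 ± 0.16), Spire1, an actin nucleator (-1.36 ± 0.32), and Nt5dc2 (-1.35 ± 0.20), and Mysm1 was at -0.38 ± 0.15 (adjusted p = 0.327). In total 87 genes rose and 198 fell, 285 together, against 627 by DESeq2, 446 by voom, 466 by limma-trend and 502 with background as a covariate. Leaving out C2 gave 148, B1 163, B3 171 and C3 184. The calls of Sapcd2 and Spire1 ended without B1 (0.15 and 0.20), B5 (0.076 and 0.084) or C2 (0.11 and 0.25), and that of Spire1 also without B3 (0.20) or C5 (0.12).

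In CD150-positive cells (7 against 2) 10 of 41 p53 targets rose (27 up and 1 down adjusted over the list alone; median 0.89, adjusted p = 2.3e-28, and 8.92e-05 with an estimated correlation; 0.73 without the P and W libraries). Bbc3 rose from 2.39 ± 0.412 to 19.4 ± 3.36 CPM (3.01 ± 0.30, adjusted p = 3.4e-05), and Cdkn1a (4.00 ± 0.49), Phlda3 (3.84 ± 0.54) and Mmp2 (2.89 ± 0.35) had the other largest rises. Mysm1 was at -0.65 ± 0.14 (adjusted p = 0.0835). Interferon response genes lay higher with a median of 0.70 and 12 called when adjusted over the list alone (adjusted p = 1.1e-13, but adjusted p = 0.286 with an estimated correlation; 0.63 without the P and W libraries). Of 78 ribosomal protein genes 1 fell, Rpl36a (-1.19 ± 0.18), with 22 adjusted over the list alone (median -0.32, adjusted p = 1.1e-08, but adjusted p = 0.685 with an estimated correlation; -0.21 without the P and W libraries), and Rpl22l1 fell by 1.29 on the log2 scale. The mitosis list had a median of -0.27 (adjusted p = 0.00488, but adjusted p = 0.685 with an estimated correlation; -0.36 without the P and W libraries; adjusted p = 0.130 without C1-4). Apob (-3.06 ± 0.60) and Mgam, an intestinal glucosidase (-2.41 ± 0.43), fell against the high values of C2-5 and were at -1.01 and -0.62 without that library. In total 19 genes rose and 5 fell, against 13 and 0 without the P and W libraries, 13 and 7 with RLE factors and 73 and 34 by DESeq2. The 24 calls became 5 without C2-5 and 7 without C1-4. The calls of Phlda3, Rpl22l1 and Rpl36a ended without C1-4 (0.096, 0.44 and 0.33) or C2-5 (0.14, 0.18 and 0.057). That of Rpl22l1 also ended without B3 (0.060), and that of Apob without B3, B5, P2 or P3 (0.10, 0.057, 0.075 and 0.098). Without the P and W libraries the calls of Apob, Mgam, Rpl22l1 and Rpl36a ended (0.249, 0.145, 0.143 and 0.0611). The median of all genes in this comparison was -0.09 with TMM and 0.05 in the deposited CPM.

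Whether the effect of Mysm1 loss differed between populations was tested directly. Ak1 rose less in CD150-positive than in CD150-negative cells (difference -1.94 ± 0.27, adjusted p = 0.0018), and Cox6b2, a subunit of cytochrome c oxidase, also differed (-1.52 ± 0.26, adjusted p = 0.0396). These were the only 2 genes called by edgeR, with 801 at an unadjusted p under 0.05, while DESeq2 called 14, voom 9 and limma-trend 5. Without the P and W libraries none was called by edgeR, with 1033 at an unadjusted p under 0.05 and an adjusted p of 0.068 for Ak1 and 0.13 for Cox6b2. The call of Cox6b2 also ended without any 1 of 10 libraries, which were A2, A3, D3 and D4 of CD150-negative cells (0.23, 0.14, 0.093 and 0.28) and A1, A2, A4, D1, D3-4 and W1 of CD150-positive cells (0.31, 0.29, 0.38, 0.094, 0.14 and 0.052). The difference for Bbc3 was 0.11 ± 0.33 and that for Mysm1 -0.20 ± 0.18 (adjusted p = 1.00 for both). Over 20385 genes the effects had a Pearson correlation of 0.28 and a Spearman correlation of 0.39, and genes are not independent replicates. Of 183 genes called in CD150-negative cells 97.8% had the same sign in CD150-positive cells, and 46 were up and 8 down in both, where independent lists would share 0.517 and 0.04. For Mysm1 loss without Puma the effects in both populations had a Pearson correlation of -0.07 and a Spearman correlation of -0.06 over the same genes. Of 285 genes called in CD150-negative cells 94.0% had the same sign in CD150-positive cells, and 17 were up and 3 down in both, where independent lists would share 0.0811 and 0.0486. Some libraries carry the same name in both populations. Their deviations from the group mean had correlations of 0.0926, 0.756, 0.615 and 0.120 for A1, A2, A3 and D2. For B1, B3 and B5 these were -0.0228, 0.286 and -0.208. Both A2 libraries also stood alone in their population in Xist and Ddx3y, which goes with a shared source of A2. The labels do not state one, so a shared source of A2 and of other libraries stays open. It could raise the overlaps above those of independent lists.

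Whether the effect of Mysm1 loss differed with Puma was tested as the effect in Puma-/- cells minus that in Puma+/- and wild-type cells. An effect of Puma heterozygosity therefore also enters this difference. In CD150-negative cells edgeR called 3 genes, with 1595 at an unadjusted p under 0.05, while DESeq2 called 70, voom 63 and limma-trend 1. Sox11 differed by 3.21 ± 0.48 (adjusted p = 0.0274) and Gem by -1.82 ± 0.27 (adjusted p = 0.0265), with Gem between 91.1 and 115 CPM in A1 to A3 and at 37.1, 37.9 and 28.5 in B1, B3 and B5. Bc1, a noncoding RNA named after its value was seen, differed by 6.93 ± 0.87 (adjusted p = 0.0073) at a mean log2 CPM of 1.15, a call that ended without A2 or B1 (0.0535 and 0.0505). The Sox11 call ended without A1, A2, B1, B3, B5, C2, C5, D2, D3 or D4 (0.11, 0.14, 0.20, 0.20, 0.053, 0.073, 0.14, 0.13, 0.067 and 0.13). The Gem call ended without the same libraries except D4 (0.11, 0.057, 0.073, 0.077, 0.059, 0.073, 0.051, 0.060 and 0.090). Bbc3 differed by -0.10 ± 0.38 (adjusted p = 0.973) and Mysm1 by -0.35 ± 0.21 (adjusted p = 0.730). In CD150-positive cells edgeR, DESeq2, voom and limma-trend called 0 genes, with 309 at an unadjusted p under 0.05, and 219 without the P and W libraries. The smallest p-values were those of Plxdc2 (1.73 ± 0.42), Lypd6b (-2.12 ± 0.55), Tpm4, a tropomyosin (-1.48 ± 0.40), and Mdga1 (0.93 ± 0.25), Bbc3 was at 0.57 ± 0.34 and Mysm1 at -0.46 ± 0.19, all with an adjusted p of 1.00.

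The effects of Mysm1 loss with and without Puma share no libraries, so they could be set side by side. Over 21168 genes in CD150-negative cells the Pearson correlation was 0.04 with a jackknife SE of 0.162, and the Spearman correlation was 0.06. Among genes at a mean log2 CPM of 4 or more the Pearson correlation was 0.41. Of the 184 genes called with Puma 94.6% had the same sign without it. Called in both were 58 genes up and 10 down, where independent lists would share 0.555 and 0.458, and 2 genes were called in opposite directions. Over 20944 genes in CD150-positive cells the Pearson correlation was 0.34 with a jackknife SE of 0.355, and the Spearman correlation was 0.52. The Pearson correlation was 0.62 among genes at a mean log2 CPM of 4 or more and 0.32 without the P and W libraries. Of 95 called genes 98.9% had the same sign. There 19 genes were called up and 3 down in both, where independent lists would share 0.0708 and 0.00406.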

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

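The tests of Rpl22l1 with its copy, of the naming series and of the ribosomal protein list and the quantities searched for libraries far from their group were chosen after the results had been seen, and background reads were chosen as an explanation after the data but before the mitosis test.

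Of 45 group values searched for a library far from the others of its group, 4 stood out, and chance alone marks about 1 in 20. Only groups of at least 4 libraries were searched, which left out all CD150-negative groups and the Puma-/- group of CD150-positive cells. In CPM of the library totals, without TMM scaling, Xist was at 333 in the CD150-positive library A2. Igj, an immunoglobulin joining chain gene, was at 2494 in the CD150-positive library B1, and receptor genes taken as background were at 8186 in the CD150-positive library D2. Immediate early genes had a mean log2 CPM of 4.57 in W1.

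Mitosis and ribosomal protein transcripts were lower in CD150-negative libraries labelled Mysm1-/-Puma-/- than in those labelled Mysm1-/-Puma+/-. With log2 receptor-gene CPM as a covariate the mitosis median was -0.78, past the bound of -0.40 written beforehand, and the one closest to 0 with 1 library left out was -0.65, which argues against background reads or a single library as the cause of the mitosis change, although the count of called genes rested on single libraries. For the ribosomal protein list the covariate gave -0.37, short of that bound, so background reads stay open there. Without B1, the lowest B library, its median came closest to 0 (-0.39), also short of the bound. The other B libraries lay below every A library by 0.26 in mean log2 CPM (larger SD 0.0942). Leaving out B1 could not narrow that gap, so the gap does not test a single library as the cause. The list stayed lower without any 1 library, but a part of a single library in its size stays open. Differences between animals, litters or processing days that go with the genotype could not be tested, since the labels give none of them. A biological difference that depends on Puma stays a hypothesis, and each list had an adjusted p of 0.256 with an estimated correlation.

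Rpl22l1 was lower with Mysm1 loss in both populations. Its copy Gm15421, 399 bases on chromosome 5 from 22034139 to 22034537 on the minus strand, aligned to Rpl22l1 over 395 bases at 99.5% identity. Summed over both genes the log2 fold change was -1.46 ± 0.18 (SE) in CD150-negative and -1.13 ± 0.21 in CD150-positive cells (adjusted p = 0.0002 and 0.0088), which argues against reads moved between these 2 genes. A difference that comes with the Mysm1 genotype stays open, as does one that comes with other copies.

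Immediate early transcripts differed among CD150-positive libraries along the naming series. Within a group the P or W library was higher in 15 of 15 pairs with libraries of the other series, although P1 lay at 2.84 and B6 at 2.82, and the result was found and tested on the same libraries. P2, P3 and W1 lay at 4.09, 4.23 and 4.57. Cell handling before lysis, which induces these genes, and a difference between preparation batches could each give such values and cannot be told apart here, since the labels give no dates.

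Effects of Mysm1 loss that differed between populations were those of Ak1 (-1.94) and Cox6b2 (-1.52), each by a test of the difference. By the same kind of test, lists differed with medians of -0.24 for p53 targets, 0.29 for multipotent progenitor and lymphoid priming, 0.19 for DNA replication, 0.37 for mitosis, 0.24 for interferon response, -0.17 for antioxidant genes, 0.17 for DNA repair, -0.11 for oxidative phosphorylation, -0.97 for immediate early genes and -0.47 for abundant noncoding RNA. None of these lists held with an estimated correlation (adjusted p of 0.149 or more). Without the P and W libraries none of these genes was called by edgeR, beside 1033 at an unadjusted p under 0.05. The list medians were then -0.10, 0.73, 0.21, 0.38, 0.36, -0.15, 0.23, -0.11, -0.33 and -0.42 in that order, and DNA replication (adjusted p = 0.167) and immediate early genes (0.468) were no longer called. Only mitosis and abundant noncoding RNA stayed called without any 1 library. Without the CD150-positive library A4 interferon response and oxidative phosphorylation turned (-0.0237 and 0.0713, adjusted p = 0.860 and 0.513), and p53 targets (0.0782) and antioxidant genes were not called. Without the CD150-negative library A3 p53 targets (0.0886), DNA replication (0.707), antioxidant genes (0.0742), DNA repair (0.238) and immediate early genes (0.0886) were not called, and without A1 progenitor (0.228) and interferon genes (0.992) were not.

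Effects of Mysm1 loss that differed with Puma in CD150-negative cells were those of Sox11 (3.21), Bc1 (6.93) and Gem (-1.82). Lists differed there with medians of -0.24 for p53 targets, -0.22 for the Bcl2 and caspase list, -0.47 for ribosomal proteins, -0.26 for ribosome biogenesis, -0.58 for megakaryocyte genes, -0.49 for DNA replication, -0.58 for mitosis, 0.47 for interferon response, -0.40 for antioxidant genes, -0.18 for DNA repair, -0.56 for oxidative phosphorylation and -0.19 for integrated stress response (adjusted p of 0.369 or more with an estimated correlation). The Bcl2 and caspase list was not called without A3 (0.0920), interferon response without C3 (0.0895), DNA repair without D4 (0.0682) and integrated stress response without A3, B1, C2 or D4 (0.199, 0.0590, 0.131 and 0.0610). In CD150-positive cells lists differed with medians of -0.26 for ribosomal proteins, 0.0455 for ribosome biogenesis, 0.0616 for stem cell genes, 0.23 for erythroid genes, -0.41 for megakaryocyte genes, -0.54 for T and NK cell genes, -0.52 for mitosis, 0.26 for interferon response, -0.24 for oxidative phosphorylation and 0.82 for immediate early genes (adjusted p = 0.702 for each with an estimated correlation). Without the P and W libraries these were -0.0848, 0.000106, -0.0304, 0.60, 0.0942, 0.14, -0.52, 0.16, -0.10 and -0.13. Only erythroid genes, mitosis and interferon response were then still called. Ribosomal proteins, stem cell genes and oxidative phosphorylation had an adjusted p of 0.390, ribosome biogenesis 0.867, megakaryocyte and T and NK cell genes 0.731 and immediate early genes 0.666. The erythroid list was not called without A1, A2, B1, B5, C2-5, D2 or D3-4 (0.858, 0.244, 0.0888, 0.143, 0.904, 0.0658 and 0.105). Without C1-4 ribosomal proteins (0.389), megakaryocyte genes (0.0507) and oxidative phosphorylation (0.516) were not called. Only T and NK cell genes, mitosis, interferon response and immediate early genes stayed called without any 1 library.

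Other splits of the same libraries were fitted to ask whether chance can be excluded for the counts of genes. For Mysm1 loss in CD150-positive cells 1 of 35 splits, the real one, called as many as 95 genes, and the highest other called 43. That other split set A1, A2, D1 and D2 against the remaining libraries. A structure of the samples that goes with sample number therefore stays open there. For the wild-type populations 1 of 35 splits called as many as 1560, and the highest other called 778. That share of 0.0286 is the smallest that 35 splits can give, and several comparisons were split. It argues against chance in both but does not exclude it. For loss of both genes in CD150-positive cells 2 of 100 splits called as many as 61. The other of these called 270 and parted the libraries exactly by naming series, and without that series the real split called 38 genes. For the difference with Puma in CD150-negative cells 2 of 100 splits called as many as 3, and the highest other called 532. For the difference between populations 9 of 100 splits called as many as 2, with 107 as the highest other. For these 2 differences the splits shuffled the genotype labels, so the effect of Mysm1 loss itself could enter the difference. Their counts therefore give no rate for chance, which stays open, and do not show a structure of the samples.

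For Puma loss on Mysm1 loss in CD150-positive cells all 100 of 100 splits called as many as the 0 genes that edgeR called, beside 797 at an unadjusted p under 0.05 and 3 by DESeq2, 0 by voom and 0 by limma-trend. The highest other split called 785, which points to a structure of the samples. It set A1, B3, P1 and P2 against the others. Their receptor-gene background was 0.424, 0.423, 0.182 and 0.406 times the median of the population. All others except A3 (0.415) were at 0.946 or more. Whether background reads gave this structure was not tested. In CD150-negative cells each comparison had 10 splits, too few for a share under 0.05. The real and highest other counts were 184 and 1 for Mysm1 loss, 263 and 0 for Puma loss on Mysm1 loss, 490 and 3 for loss of both genes, and 285 and 0 for Mysm1 loss without Puma, each with 1 split as high as the real one. For Puma loss alone they were 0 and 0 by edgeR, in 10 of 10 splits, beside 324 at an unadjusted p under 0.05 and 2 by DESeq2, 0 by voom and 0 by limma-trend.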

How the results depend on the processing

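The 2 alternatives for background reads were chosen after the data had been seen, and the others were planned. The cause of the changes given here was not tested, except that leaving out libraries lowers the number of samples.

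In CD150-negative cells, counts of called genes are given for Mysm1 loss (184), Puma loss on Mysm1 loss (263), loss of both genes (490), Puma loss alone (0), Mysm1 loss without Puma (285) and the difference with Puma (3). DESeq2 gave 427, 1404, 1029, 2, 627 and 70 in that order. Voom gave 858, 1724, 1105, 446 and 63 for these except Puma loss alone. Limma-trend on deposited CPM gave 297, 906, 466 and 1 for Mysm1 loss, loss of both, Mysm1 loss without Puma and the difference. The compared groups alone gave 2 for Puma loss on Mysm1 loss. Without the high-background library B1 the counts were 64 for Puma loss on Mysm1 loss, 258 for loss of both, 163 for Mysm1 loss without Puma and 0 for the difference. With background as a covariate they were 394 for Mysm1 loss, 837 for loss of both, 502 for Mysm1 loss without Puma and 5 for the difference.

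In CD150-positive cells DESeq2 gave 244 for Mysm1 loss (95), 3 for Puma loss on Mysm1 loss (0), 207 for loss of both (61) and 107 for Mysm1 loss without Puma (24). Voom gave 58 for the last, and limma-trend gave 131 for loss of both and 63 for the last. The compared groups alone gave 52 for Mysm1 loss. Without the P and W libraries loss of both had 38 and Mysm1 loss without Puma 13. Without high-background libraries the last had 9, and with background as a covariate Puma loss on Mysm1 loss had 1 and loss of both 108. For the difference between populations (2), DESeq2 gave 14, voom 9, limma-trend 5, no filter 1 and leaving out P and W 0. For the wild-type populations (1560) voom gave 2503 and the covariate 2613. RLE factors kept every count of at least 20 genes within 1.5 times. Of 151 list calls 9 held with an estimated correlation and 29 by fry. The correlation of Mysm1 effects with and without Puma in CD150-negative cells was 0.04, and 0.41 among genes at a mean log2 CPM of 4 or more.

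With 1 library left out, CD150-negative counts ran from 98 to 328 for Mysm1 loss, 1 to 1086 for Puma loss on Mysm1 loss, 250 to 574 for loss of both, 0 to 0 for Puma loss alone, 148 to 336 for Mysm1 loss without Puma and 0 to 23 for the difference with Puma. CD150-positive counts ran from 60 to 107, 0 to 9, 46 to 90, 0 to 0, 5 to 30 and 0 to 0 in that order. The wild-type populations ran from 984 to 1495, the difference between populations from 1 to 3 and the list calls from 133 to 158. The correlation with and without Puma ran from -0.06 to 0.14 in CD150-negative and 0.04 to 0.41 in CD150-positive cells. Without C1-4 or C2-5, the lone remaining Puma-/- library of CD150-positive cells was assumed to vary like the other groups.

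Lists whose tested direction changed are given next, as medians with the range over fits without 1 library. In CD150-negative cells interferon response ran from -0.18 (without A3) to 0.14 for Mysm1 loss. Erythroid genes ran from -0.69 to 0.80 (without A3) for Puma loss on Mysm1 loss, where background as a covariate gave 0.68, and from -1.04 to 0.63 (without A3) for the difference with Puma. Granulocyte and monocyte genes ran from -0.33 (without B5) to 0.71 for that difference. Ribosomal proteins ran from -0.0727 to 0.12 (without D3) for Puma loss alone. In CD150-positive cells erythroid genes ran from -0.20 (without A1) to 0.67 for Puma loss on Mysm1 loss, and were at -0.15 without high-background libraries for the difference with Puma. For Puma loss alone ribosomal proteins ran from -0.10 to 0.14 and stem cell genes from -0.18 to 0.17, each highest without C2-5. For the difference with Puma stem cell genes ran from -0.10 to 0.31 and ribosome biogenesis from -0.0520 to 0.23, each lowest without C2-5. The difference between populations ran from -0.20 to 0.0713 for oxidative phosphorylation, from -0.0629 to 0.11 for ribosome biogenesis and from -0.0237 to 0.48 for interferon response, the direction changing without the CD150-positive library A4. Immediate early genes ran from -0.86 to 0.14 (without W1) for Mysm1 loss. Without P and W they were at 0.14 for Mysm1 loss, 0.26 for Puma loss alone and -0.13 for the difference with Puma, T and NK cell genes were at 0.14 for that difference, and megakaryocyte genes were at 0.0720 for Puma loss on Mysm1 loss. Without P and W the median also crossed 0, with the call lost, for megakaryocyte genes (-0.41 to 0.0942) and stem cell genes (0.06 to -0.0304) in the difference with Puma, and for immediate early genes (0.56 to -0.00797) in Mysm1 loss without Puma.

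Of 274 values of named genes none changed sign while called, though not every value could be tested in every setting. Those that stopped being called numbered 2 with DESeq2, 1 with RLE factors, 6 without the filter, 14 with voom, 17 with limma-trend, 63 with the compared groups alone, 68 without high-background libraries, 19 without P and W and 11 with background as a covariate. Over the fits without 1 library 398 values lost their call and 1630 kept their result.

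With sample number as a block the counts in CD150-negative cells were 54 for Mysm1 loss and 0 for Puma loss on Mysm1 loss (edgeR). They were 81 for Mysm1 loss without Puma and 0 for the difference. Loss of both was not tested so in CD150-negative cells, since only B3 and D3 of its libraries share a number. In CD150-positive cells Mysm1 loss had 322. That fit left out C1-4, C2-5, D3-4 and the P and W libraries and set A1 to A4 against D1 and D2. The 322 therefore cannot be credited to the block alone. With this block 74 values of named genes lost their call and 70 kept their result. Correlations between libraries of the same number ran from -0.519 to 0.380 in CD150-negative cells, with 4 of 11 pairs above 0.1. In CD150-positive cells such correlations ran from 0.0121 to 0.442, with 2 of 5 above 0.1. Pairing by number within a population was therefore not shown, but it stays open. In CD150-positive cells A2 and D2 had 0.442, and A1 and D1 had 0.275. The highest other split for Mysm1 loss there set A1, A2, D1 and D2 against the remaining libraries. The pairs A1 and B1, A3 and B3, and B1 and D1 had 0.0632, 0.0121 and 0.0972. Those of the same identifier across populations ran from -0.208 to 0.756 and exceeded 0.1 in 4 of 7 pairs, so a shared source of some libraries across populations stays open. With the identifier as a random block the wild-type populations had 1938 calls and the difference between populations 3. Of the named genes 50 values then kept their result and 1, Egr1 in the wild-type populations, lost its call. No call of Bbc3 was lost in the leave-out fits of the 6 comparisons of Mysm1-/- with wild-type Mysm1.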

Other observations

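The tests of these genes were planned as members of lists, and the genes were chosen after the results had been seen.

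H2-Eb1 and H2-Ab1 encode chains of MHC class II, which presents peptides to T cells. H2-Eb1 rose in CD150-positive cells by 1.74 ± 0.32 (SE) with Mysm1 loss (adjusted p = 0.0090) and by 2.08 ± 0.30 with loss of both genes (adjusted p = 0.00069). H2-Ab1 rose there by 1.42 ± 0.27 and 1.41 ± 0.25 (adjusted p = 0.0124 and 0.0070), the former call ending without A3, D2, D3-4 or W1 (0.062, 0.063, 0.058 and 0.052). Both comparisons used the same wild-type libraries. With Mysm1 loss the calls of H2-Eb1 and H2-Ab1 also ended without the high-background libraries (0.079 and 0.083). Ier5, an immediate early response gene, rose in CD150-negative cells by 1.46 ± 0.16 with Mysm1 loss, 1.37 ± 0.16 with loss of both genes and 1.27 ± 0.16 with Mysm1 loss without Puma. In CD150-positive cells it rose by 1.14 ± 0.20 and 1.25 ± 0.18 with Mysm1 loss and with loss of both genes, and was at 1.16 ± 0.24 with Mysm1 loss without Puma (adjusted p = 0.0571).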
